A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

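Total RNA was hybridized to 10 single-channel Affymetrix yeast arrays, per the labels' protocols. The cells were *Saccharomyces cerevisiae* CEN.PK113-7D, a MATa strain, grown without oxygen in glucose-limited retentostats, in which fresh medium enters while the biomass is held back. A pair of duplicate cultures, each started from its own chemostat, was sampled after 14 days (T0, calorie restriction) and then at 10, 30, 60 and 120 min after the feed was stopped (starvation). Each of the 5 times thus has 2 arrays, 1 per culture, and the samples of a culture are serial. RNA was prepared from 50 mg of biomass at T0 and from 100 mg at every starvation time, so the amount of biomass goes with each comparison against T0.

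The deposited values are linear intensity values per probe set, 1 for each of 9335 probe sets on each array. Per the submitters' processing notes GCOS 1.2 was involved, in a role they do not state. The summary method, the background step and the scaling target of the authors are not given in the sources used here. Medians of the deposited intensity ranged from 42.9 to 90.4 between arrays (2.11-fold) and 2% trimmed means from 155.5 to 289.6 (1.86-fold), also between arrays of the same time, so the arrays were not on a common level. The plan, made before the data were examined, took the deposited scaling as it was and kept quantile normalization as an alternative. Because of the unequal levels the order was turned around: quantile normalization was used for the values given here, and the values as deposited are an alternative. All other main choices, the gene lists, the rule for naming genes and the tests of the comparisons were fixed before the data were examined.

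The deposited values were quantile normalized over all 9335 probe sets, values under 12 were set to 12, and log2 was taken. Of the 190 values of 19 bacterial and mouse probe sets without spiked RNA, 1 was above 12. A probe set was tested if its annotation named exactly 1 yeast gene (6504 probe sets, all 6504 found by Entrez identifier in the RefSeq gene table, which was used for names only) and its mean deposited intensity was at least 12. This left 5759 probe sets of 5356 genes. Left out were 745 dim probe sets, 328 with several genes, 2443 with no named gene and 60 control probe sets. In gene lists and for named genes, the probe set with the highest mean log2 signal stands for a gene.

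Group means were fitted over all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes without trend or robust option), with 5 residual degrees of freedom and 6.79 prior degrees of freedom. Each starvation time was compared with T0, each time with the one before it, and all 4 starvation times with T0 at once in a moderated F test. A return was sought as a change by 10 min followed by the opposite change from 10 to 120 min. Adjusted p is after Benjamini-Hochberg over the probe sets of a contrast, and a probe set passed at an adjusted p under 0.05. All tests were two-sided unless stated. Values after ± are limma's standard errors (SE) of a log2 change with n = 2 arrays per time. Signals are normalized intensities, given as the geometric mean of the 2 arrays of a time. The number of arrays limits the precision: the median SE of a log2 change was 0.28.

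Of 41 gene lists written down beforehand, 40 had at least 5 measured genes. Each was compared with all other genes by limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 160 tests of 40 lists and 4 times. A list's value is the median log2 change of its measured genes. Beside the number of its genes that passed over all genes stands the number adjusted over the list alone. The core histone list had 4 measured genes and was not tested.

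Genes were named by rule: at each time the 6 largest rises and 6 largest falls with a standard symbol among those that passed, with a mean signal of at least 50 and both starved arrays beyond both T0 arrays, and up to 2 per direction with only a systematic name; up to 4 members of each list with the largest change at 120 min; a fixed set of markers, whatever their values; and for intervals the 3 largest rises and falls. Genes named outside the rule are said to be so.

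Alternatives changed 1 choice at a time. They were the values as deposited, centring on the median, a floor of 50, log2 of value plus 1 or plus 16, no filter, a minimum mean of 50, all probe sets, a replicate block (fixed or random), eBayes with trend and robust, a fit of the compared arrays alone, an adjusted p under 0.01, a minimum of 2-fold, camera with an estimated correlation, fry, all probe sets of a gene, and each array left out in turn. Trimmed-mean scaling, spike-in scaling and leaving out non-coding RNA were added after seeing the data. The spike-ins are hybridization controls, so scaling to them does not give amounts of RNA per cell. The culture numbers tie the starved samples to a retentostat culture, so the samples are paired by culture. Deviations from the group means correlated by more than 0.1 in 4 of 10 pairs of times (range −0.01 to 0.33, median 0.08), and the consensus correlation of the random block was 0.05. The unblocked fit was kept, and the blocked value is given where a count moved by more than 1.5 times.

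The fit and the list test were tested on simulated data for 120 min against T0 with 5759 probe sets, 10 simulations and 200 changed probe sets in each. At 1.5-fold 1.8% of the changed probe sets were found, at 2-fold 31.6%, at 3-fold 74.2% and at 4-fold 87.2%, and 3.7% of the calls were false. The ribosome biogenesis list, with all of its 99 measured genes lowered by 0.3 on the log2 scale, was found in 10 of 10 simulations. Genes varied independently in these simulations and no shorter list was tried, so they do not show how correlated or short lists fare. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.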

Results

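Transcript levels of *Saccharomyces cerevisiae* were measured on 10 arrays: 2 from calorie-restricted retentostat cultures (T0) and 2 each after 10, 30, 60 and 120 min of starvation. The calorie-restricted cells still grew at an estimated specific rate of 0.0016 per h after 14 days on a glucose feed, and starvation began when that feed was stopped. Deposited intensities had medians of 42.9 to 90.4 per array, and 20.1% to 27.0% of the probe sets of an array lay under the floor of 12. Replicate arrays correlated across probe sets with a Pearson coefficient of 0.966 to 0.979 after normalization, and the replicate SD was 0.28 to 0.36 log2 units per array. The first principal component held 43.1% of the variance and ordered the times in both cultures, from −27.78 and −27.69 at T0 to 22.79 and 26.3 at 120 min. The comparisons against T0 ask how transcripts change when a very slowly growing cell loses its energy source. All 4 of them share the same T0 arrays.

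**Figure D1:**
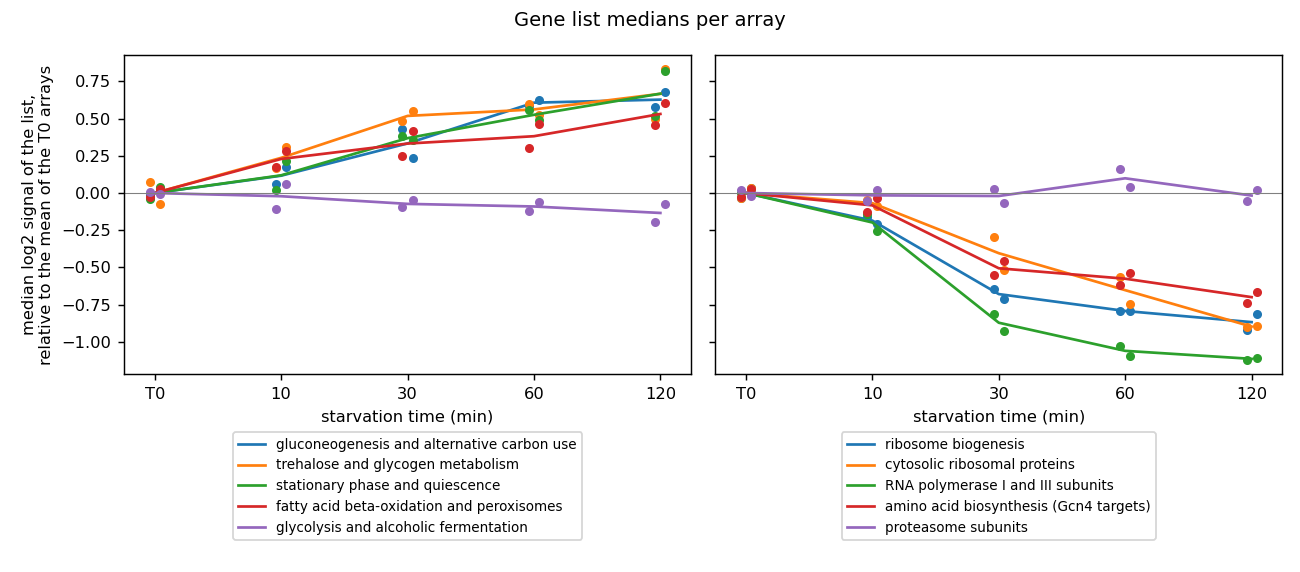
Median log2 signal of gene lists on each array relative to the mean of the T0 arrays (y axis) against starvation time in min (x axis). Points are arrays and lines join the means of the 2 arrays of a time; ribosome biogenesis lies at −0.924 and −0.812 on the 120 min arrays.

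Within 10 min of starvation, relative to all other genes, gene lists of ribosome synthesis were lower than at T0. The lists of storage carbohydrates and of beta-oxidation and peroxisomes were higher. None of the genes of these lists passed over all genes. The 99 measured ribosome biogenesis genes fell relative to all other genes, with a median log2 change of −0.24 (camera adjusted p = 2.45e-06). The 24 subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, fell by the same median of −0.24 (adjusted p = 0.00169, and adjusted p = 0.112 with an estimated correlation). Translation factors had a median of −0.09 over 33 genes (adjusted p = 0.0275, and adjusted p = 0.134 with an estimated correlation). Gcn4 targets, which make amino acids, had a median of −0.09 over 62 genes (adjusted p = 0.0449, and adjusted p = 0.255 with an estimated correlation). The trehalose and glycogen list was higher, with a median of 0.15 over 23 genes (adjusted p = 0.00936, and adjusted p = 0.248 with an estimated correlation). The list of fatty acid beta-oxidation and peroxisomes was at 0.16 over 39 genes (adjusted p = 0.0358, and adjusted p = 0.120 with an estimated correlation). As deposited and not taken relative to all genes, the medians of these 2 lists were −0.03 each. In all 6 lists the medians of both 10 min arrays lay beyond those of both T0 arrays.

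With quantile normalization and the floor of 12 no single probe set passed at 10 min. By limma 0 were higher and 0 lower, and at an unadjusted p under 0.05 there were 152 higher and 190 lower, where 288 are expected by chance. A floor of 50 gave 2 higher and 16 lower, and trimmed-mean scaling 0 and 1. The smallest adjusted p was 0.354. AAC3, the anaerobic ADP/ATP carrier of mitochondria, was at −1.79 ± 0.30 (adjusted p = 0.354). NSR1, the yeast nucleolin, was at −1.52 ± 0.29 and HIS7 of histidine synthesis at −1.49 ± 0.29 (adjusted p = 0.494 for both). Adjusted over the list alone, 1 ribosome biogenesis gene fell and 0 rose. Ribosomal RNA signal over that of the median transcript was 6.66 at 10 min and 5.74 at T0. The ratio of 3' to 5' signal of actin, a sign of RNA integrity, was 2.29 and 1.68 at 10 min and 1.4 and 1.24 at T0. That of TBP was higher than at T0 in culture 1 and lower in culture 2.

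The ribosome biogenesis call held whichever array was left out, and the other 5 did not. Lists higher went from 2 to 0 without 10 min replicate 2 or T0 replicate 2, and lists lower from 4 to 1 without 10 min replicate 2. Without 10 min replicate 2 the adjusted p was 0.110 for the polymerases, 0.224 for trehalose and glycogen and 0.234 for beta-oxidation. Trehalose and glycogen was also lost without T0 replicate 2, and beta-oxidation without either T0 array. Translation factors reached 0.147 without T0 replicate 1 and were lost without either 10 min array. Gcn4 targets reached 0.144 without 10 min replicate 1 and were lost in 8 of 10 cases, every array but those of 30 min. They also missed the threshold under each of the 4 other scalings and with the replicate block (adjusted p = 0.0501). Translation factors did so as deposited (0.0842) and with spike-in scaling (0.0926), and beta-oxidation with trimmed-mean scaling (0.0523) and a floor of 50 (0.113). With fry the adjusted p was 0.0582 for translation factors, 0.107 for trehalose and glycogen and 0.173 for Gcn4 targets, and with all probe sets of a gene it was 0.0648 for Gcn4 targets.

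After 30 min, a few single transcripts of ribosome synthesis and that of the hexokinase HXK2 were several-fold lower. NSR1 fell 9.98-fold, from a signal of 361.8 to 36.3 (log2 change −3.32 ± 0.29, adjusted p = 0.000562). RPA49, a subunit of RNA polymerase I, fell 5.10-fold (−2.35 ± 0.35), and RPA12 of the same enzyme, at the floor on 1 of the 2 arrays, at least 7.73-fold (adjusted p = 0.000859). UTP18 of the small-subunit processome fell 4.77-fold (−2.25 ± 0.30) and HMT1, an arginine methyltransferase, 5.97-fold (−2.58 ± 0.34). HXK2 fell 5.83-fold, from 384.1 to 65.8 (adjusted p = 0.00434). The largest rise was that of SNR6, the U6 spliceosomal RNA, at 6.27-fold (2.65 ± 0.29, adjusted p = 0.00118). SNR6 is among the RNAs without poly(A) tails, which were higher as a class at 30 min. CIN5, a stress-related transcription factor, rose 5.37-fold (2.43 ± 0.33, 198.2 to 1065) and NRS1 3.98-fold (1.99 ± 0.25).

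The rule named further rises in BOP2 (1.90 ± 0.30), the protein kinase gene PRR2 (1.79 ± 0.26), YNL194C (1.53 ± 0.30) and YJR115W (1.32 ± 0.25). It also named the tRNA YNCE0014W (2.19 ± 0.42), whose probe set is of a family type, so its identity is uncertain. Falls were those of YKL068W-A (−2.35 ± 0.28), YGL039W (−1.30 ± 0.28) and the stress regulator MSN4 (−1.18 ± 0.29, adjusted p = 0.0358). Some of these calls were lost with 1 array left out. Without 30 min replicate 1 the adjusted p was 0.0518 for BOP2, 0.0832 for YNCE0014W and 0.175 for MSN4. Without T0 replicate 1 it was 0.0975 for YJR115W and 0.122 for YGL039W, and without 30 min replicate 2 it was 0.0905 for YNL194C. The call of BOP2 was also lost without T0 replicate 1, that of YJR115W without 30 min replicate 1 and that of YNL194C without either T0 array. That of YNCE0014W was also lost without 30 min replicate 2 or T0 replicate 2, that of YGL039W without either 30 min array or T0 replicate 2, and that of MSN4 without any T0, 30 min or 60 min array.

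Relative to all other genes, lists of growth genes were lower at 30 min and lists of reserves, stress and recycling higher. None of the higher lists passed with an estimated correlation. Of 99 ribosome biogenesis genes 22 fell and 0 rose (median −0.69, camera adjusted p = 1.57e-20), and 43 fell adjusted over the list alone. Among them were NOP1, the yeast fibrillarin (−1.86 ± 0.26), and ARX1, a nuclear export factor of the large subunit (−2.18 ± 0.24). Of 24 polymerase subunits 10 fell (median −0.90, adjusted p = 1.32e-10), and 15 adjusted over the list alone. Of 81 cytosolic ribosomal protein genes 8 fell (median −0.46, adjusted p = 3.37e-09), and 22 adjusted over the list alone. Of 62 Gcn4 targets 13 fell (median −0.43, adjusted p = 6.86e-08), and 21 adjusted over the list alone. Sulfur amino acid genes had 5 of 27 lower (median −0.66, adjusted p = 1.32e-05, and adjusted p = 0.0518 with an estimated correlation). Aminoacyl-tRNA synthetases had 3 of 18 lower, among them FRS1 at −1.71 ± 0.23 (median −0.67, adjusted p = 0.000320, and adjusted p = 0.0865 with an estimated correlation). Translation factors had 2 lower (median −0.43, adjusted p = 0.000776, and adjusted p = 0.0668 with an estimated correlation). Sterol synthesis had 2 of 28 lower (median −0.25, adjusted p = 0.0290, but 0.124 with an estimated correlation and 0.0542 to 0.125 under the 4 other scalings). Adjusted over the list alone, 13 sulfur, 7 synthetase, 4 translation factor and 3 sterol genes fell.

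The 7 lists that rose at 30 min held few genes that passed on their own, and each lost its call with an estimated correlation. Trehalose and glycogen had 1 gene higher and 7 adjusted over the list alone (median 0.49, adjusted p = 1.87e-05, and adjusted p = 0.112 with an estimated correlation). General stress genes had 1 of 42 higher and 1 lower, and 4 and 1 adjusted over the list alone (median 0.34, adjusted p = 0.000320, and adjusted p = 0.103 with an estimated correlation). Autophagy had 2 of 33 higher and 3 adjusted over the list alone (median 0.38, adjusted p = 0.000353, and adjusted p = 0.0556 with an estimated correlation). Beta-oxidation had 1 higher (median 0.34, adjusted p = 0.00188, and adjusted p = 0.0586 with an estimated correlation). Gluconeogenesis and alternative carbon use had 0 of 30 higher (median 0.42, adjusted p = 0.0132, and adjusted p = 0.0959 with an estimated correlation). Vacuolar hydrolases had 0 of 14 higher and 1 adjusted over the list alone (median 0.35, adjusted p = 0.0180, and adjusted p = 0.120 with an estimated correlation). Stationary phase genes had 3 of 25 higher and 2 lower, and 4 and 2 adjusted over the list alone (median 0.28, adjusted p = 0.0360, and adjusted p = 0.120 with an estimated correlation). RNAs without poly(A) tails were higher at 30 min too. The median of their 135 probe sets was 0.61, with 22 higher and 1 lower, and ribosomal RNA over the median transcript was 8.88.

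By limma 95 probe sets rose and 197 fell at 30 min, 79 and 184 of them by at least 2-fold (561 and 683 at an unadjusted p under 0.05). Each array of this comparison moved the counts by more than 1.5 times when left out. They were 11 and 66 without 30 min replicate 1, 27 and 119 without 30 min replicate 2, 17 and 65 without T0 replicate 1, and 30 and 66 without T0 replicate 2. Lists higher went from 7 to 4 without T0 replicate 2, where gluconeogenesis (adjusted p = 0.0668), vacuolar hydrolases (0.0939) and stationary phase (0.0900) missed the threshold. Vacuolar hydrolases were also lost without 30 min replicate 2, stationary phase without either 30 min array, and sterol synthesis without 30 min replicate 1 (0.136) or T0 replicate 2.

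After 60 min NSR1 was 12.2-fold lower than at T0 (−3.61 ± 0.29, adjusted p = 0.000221), HMT1 7.06-fold (−2.82 ± 0.34) and RPA49 6.28-fold (−2.65 ± 0.35). ANS1 was 4.90-fold lower (−2.29 ± 0.30) and UTP18 4.62-fold (−2.21 ± 0.30). RPA12 was at the floor on both arrays and at least 9.25-fold lower (adjusted p = 0.000347). CIN5 was 7.60-fold higher (2.93 ± 0.33), SNR6 6.88-fold (2.78 ± 0.29), NRS1 5.21-fold (2.38 ± 0.25) and BOP2 5.16-fold (2.37 ± 0.30). FAA1, a fatty acyl-CoA synthetase, was 5.64-fold higher (2.50 ± 0.34, 30.8 to 173.8). Also higher were YNL194C (2.09 ± 0.30) and the tRNA YNCD0009W (2.27 ± 0.37), again with a family probe set. YOR012W fell (−1.57 ± 0.24), as did YKL068W-A (−1.60 ± 0.28, with adjusted p = 0.0526 without 60 min replicate 2). YBL086C rose (1.41 ± 0.25, with adjusted p = 0.0514 without T0 replicate 2).

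Ribosome biogenesis at 60 min had 37 genes lower and 60 adjusted over the list alone (median −0.81, adjusted p = 1.34e-23). Polymerase subunits had 11 lower and 18 adjusted over the list alone (median −1.05, adjusted p = 2.54e-12), with RPC11 of polymerase III at −1.65 ± 0.25. Cytosolic ribosomal proteins had 23 lower and 41 adjusted over the list alone (median −0.67, adjusted p = 3.14e-16), with RPL22B at −1.80 ± 0.27. Gcn4 targets had 17 lower, and adjusted over the list alone 27 lower and 1 higher (median −0.64, adjusted p = 1.13e-08). SER2, the phosphoserine phosphatase, was at −2.69 ± 0.41. Sulfur amino acid genes had 10 lower, and adjusted over the list alone 16 lower and 1 higher (median −0.85, adjusted p = 3.88e-07). Synthetases had 5 lower and 8 adjusted over the list alone (median −0.69, adjusted p = 7.54e-06), and translation factors 4 and 7 (median −0.43, adjusted p = 9.91e-05), both with adjusted p = 0.0556 with an estimated correlation. G1/S and DNA replication genes had 6 of 45 lower and 10 adjusted over the list alone (median −0.32, adjusted p = 0.00116, and adjusted p = 0.120 with an estimated correlation). RNR1, the large subunit of ribonucleotide reductase, was at −2.06 ± 0.26. Sterol synthesis had 4 lower, also adjusted over the list alone (median −0.29, adjusted p = 0.0266, and adjusted p = 0.120 with an estimated correlation). Purine and pyrimidine synthesis had 4 of 34 lower, and 4 lower and 1 higher adjusted over the list alone (median −0.24, adjusted p = 0.0286, and adjusted p = 0.312 with an estimated correlation). ERG2 was at −1.63 ± 0.23 and URA7, a CTP synthase, at −1.96 ± 0.31.

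Of the 13 lists that rose at 60 min, those of gluconeogenesis and of beta-oxidation kept the call with an estimated correlation. Gluconeogenesis and alternative carbon use had 6 higher, and adjusted over the list alone 11 higher and 1 lower (median 0.57, adjusted p = 1.39e-05). Beta-oxidation had 2 higher and 1 adjusted over the list alone (median 0.39, adjusted p = 4.82e-05). Trehalose and glycogen had 5 higher and 7 adjusted over the list alone (median 0.54, adjusted p = 3.74e-06, and adjusted p = 0.0959 with an estimated correlation). General stress genes had 5 higher, and adjusted over the list alone 16 higher and 1 lower (median 0.41, adjusted p = 6.91e-05, and adjusted p = 0.0816 with an estimated correlation). Autophagy had 3 higher (median 0.27, adjusted p = 0.000202), and stationary phase 5 higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.46, adjusted p = 0.000776). Both had adjusted p = 0.0556 with an estimated correlation, and SPG4 of the latter was at 1.72 ± 0.28. RMD5, of a ubiquitin ligase that degrades gluconeogenic enzymes, was at 1.50 ± 0.25.

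Mitochondrial lists were higher at 60 min by small medians. The respiratory chain was at 0.25 with 0 of 39 genes higher (adjusted p = 0.00469, and adjusted p = 0.112 with an estimated correlation). Mitochondrial ribosomal proteins were at 0.19 with 0 of 74 higher (adjusted p = 0.0142, and adjusted p = 0.270 with an estimated correlation). The tricarboxylic acid cycle was at 0.21 with 1 of 19 higher and 0 adjusted over the list alone (adjusted p = 0.0321, and adjusted p = 0.182 with an estimated correlation). The ubiquitin system had 3 of 30 higher (median 0.30, adjusted p = 0.0227) and vacuolar hydrolases 0 (median 0.30, adjusted p = 0.0203). Kinase A, Snf1 and TOR signalling had 2 of 38 higher and 1 adjusted over the list alone (median 0.21, adjusted p = 0.0360), and heat shock proteins 1 of 30 (median 0.21, adjusted p = 0.0384). These last 4 lists each had adjusted p = 0.120 with an estimated correlation. The 135 untailed RNA probe sets had a median of 0.59, with 21 higher and 0 lower, and ribosomal RNA over the median transcript was 11.3.

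By limma 145 probe sets rose and 343 fell at 60 min, 115 and 305 of them by at least 2-fold (567 and 772 unadjusted). The counts were 48 and 132 without 60 min replicate 1, 36 and 143 without 60 min replicate 2, 90 and 208 without T0 replicate 1, and 64 and 127 without T0 replicate 2. Without T0 replicate 2 the lists higher went from 13 to 8. There the adjusted p was 0.210 for heat shock, 0.265 for mitochondrial ribosomal proteins, 0.191 for purine and pyrimidine synthesis, 0.0755 for sterol synthesis and 0.0907 for vacuolar hydrolases. The ubiquitin system and kinase signalling were lost there too, with highest values of 0.116 without 60 min replicate 1 and 0.0945 without 60 min replicate 2. The tricarboxylic acid cycle reached 0.142 without T0 replicate 1 and was lost without either 60 min array. Mitochondrial ribosomal proteins and purine and pyrimidine synthesis were also lost without 60 min replicate 1, and heat shock and sterol synthesis without 60 min replicate 2. With a minimum mean of 50 the tricarboxylic acid cycle (0.0935) and heat shock (0.0627) missed the threshold, as did the cycle with a floor of 50 (0.0505) and mitochondrial ribosomal proteins with fry (0.0811).

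**Figure D2:**
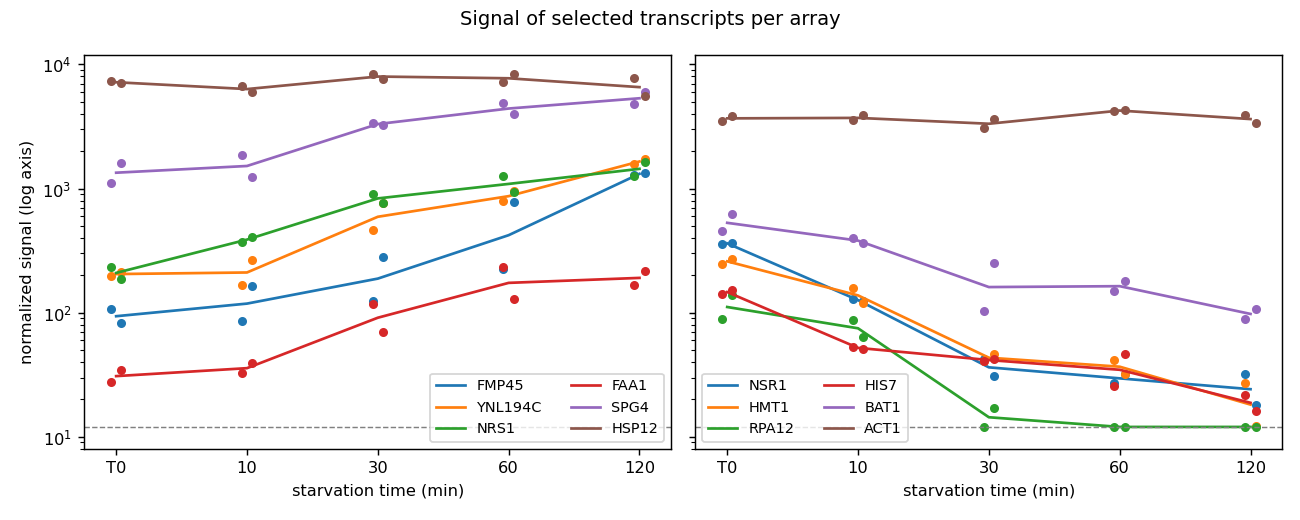
Normalized signal (log axis) of single transcripts on each array against starvation time in min; points are arrays, lines join the geometric means of the 2 arrays of a time and the dashed line is the floor of 12. FMP45 goes from 93.6 at T0 to 1313 at 120 min and NSR1 from 361.8 to 24.2, while HSP12 is at 7186 and 6560 and ACT1 at 3676 and 3628.

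After 120 min 470 probe sets had risen and 644 had fallen by limma (452 and 618 genes, and 955 and 1030 probe sets unadjusted), 329 and 471 of them by at least 2-fold. The largest rise was that of FMP45, which encodes a membrane protein of the SUR7 family, at 14.0-fold (3.81 ± 0.53, adjusted p = 0.00119, 93.6 to 1313). Its relative YNL194C rose 8.08-fold (3.01 ± 0.30, 204.6 to 1653). SNR6 was 11.6-fold higher (3.53 ± 0.29), NRS1 6.89-fold (2.79 ± 0.25), CIN5 6.52-fold (2.71 ± 0.33), BOP2 6.38-fold (2.67 ± 0.30) and FAA1 6.19-fold (2.63 ± 0.34). NSR1 was 15.0-fold lower (−3.90 ± 0.29, adjusted p = 9.43e-05), HMT1, next to the floor on 1 of the 2 arrays, at least 14.3-fold (259.1 to 18.2) and RPA12, at the floor on both arrays, at least 9.25-fold. HIS7 was 7.80-fold lower (−2.96 ± 0.29), ANS1 6.53-fold (−2.71 ± 0.30) and HEM13, a heme synthesis enzyme, 5.90-fold (−2.56 ± 0.25, 502.4 to 85.2). With systematic names, YBL086C rose (1.85 ± 0.25) and YDL177C (−1.85 ± 0.31) and YDR341C (−1.73 ± 0.22) fell.

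Ribosome biogenesis, with the most measured genes of the 40 lists, had the most falling genes at 120 min by number, but by share it came after polymerase subunits, synthetases, ribosomal proteins and sulfur amino acids. Of its 99 genes 51 fell and 0 rose, and 71 fell adjusted over the list alone (median −0.88, camera adjusted p = 2.23e-19). NOP1 was 4.76-fold lower (−2.25 ± 0.26), ARX1 went from 77.8 to 12.1, at the floor on 1 array and next to it on the other, and was thus at least 6.45-fold lower, and UTP18 was at −2.19 ± 0.30. Of 24 polymerase subunits 15 fell and 17 adjusted over the list alone (median −1.14, adjusted p = 3.36e-09), with RPC11 at −2.33 ± 0.25, RPA49 at −2.26 ± 0.35 and RPC19 at −1.97 ± 0.28. Of 81 cytosolic ribosomal protein genes 48 fell and 0 rose, and 59 fell adjusted over the list alone (median −0.93, adjusted p = 7.89e-19). RPL27B was 4.68-fold lower (−2.23 ± 0.29) and RPL16A and RPL22B were at −1.97 ± 0.29 and −1.97 ± 0.27, but RPL3 was at 0.21 ± 0.30 (adjusted p = 0.662). Translation factors had 6 of 33 lower, also adjusted over the list alone (median −0.51, adjusted p = 0.000319), and synthetases 11 of 18, or 13 adjusted over the list alone (median −0.95, adjusted p = 1.74e-05). Both had adjusted p = 0.0556 with an estimated correlation. Members were TEF4 (−1.46 ± 0.30), MES1 (−1.94 ± 0.32), TYS1 (−1.73 ± 0.28) and FRS1 (−1.69 ± 0.23).

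Lists of amino acid, sterol, nucleotide and DNA synthesis were lower at 120 min relative to all other genes, the last 3 of these without passing with an estimated correlation. Of 62 Gcn4 targets 24 fell and 1 rose, or 32 and 2 adjusted over the list alone (median −0.73, adjusted p = 1.41e-07). BAT1 of branched-chain amino acids was at −2.44 ± 0.36, SER2 at −2.32 ± 0.41 and ARO4 of aromatic amino acids at −2.27 ± 0.28, and the transcript of GCN4 itself was at −0.40 ± 0.24 (adjusted p = 0.254). Of 27 sulfur amino acid genes 15 fell and 1 rose, or 18 and 1 adjusted over the list alone (median −1.02, adjusted p = 3.85e-06), with MET5 at −1.93 ± 0.31, MET6 at −1.86 ± 0.28 and CYS4 at −1.78 ± 0.31. Sterol synthesis had 7 of 28 lower and 8 adjusted over the list alone (median −0.40, adjusted p = 0.0136, and adjusted p = 0.112 with an estimated correlation), with ERG1 at −1.86 ± 0.26 and ERG26 at −1.59 ± 0.27. Purine and pyrimidine synthesis had 6 of 34 lower and 1 higher, also adjusted over the list alone (median −0.25, adjusted p = 0.0350, but 0.332 with an estimated correlation and 0.165 to 0.262 under the 4 other scalings). URA7 was at −2.06 ± 0.31 and IMD4 at −1.70 ± 0.34. Of 45 G1/S and DNA replication genes 15 fell and 1 rose, also adjusted over the list alone (median −0.36, adjusted p = 0.00200, and adjusted p = 0.128 with an estimated correlation). RNR1 was at −2.00 ± 0.26 and the G1 cyclin CLN3 at −0.46 ± 0.36 (adjusted p = 0.396).

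Lists of other carbon sources and of reserves were higher at 120 min, though most of their genes did not pass. Of 30 gluconeogenesis and alternative carbon genes 11 rose and 0 fell, or 14 and 1 adjusted over the list alone (median 0.67, adjusted p = 6.13e-06). ALD4, the mitochondrial aldehyde dehydrogenase, went from 571.6 to 1999.8 (1.81 ± 0.24), the regulator CAT8 was at 1.62 ± 0.28 and YAT1 of carnitine acetyl transfer at 1.60 ± 0.30. PCK1, FBP1, ICL1 and ADH2 did not pass (0.34 ± 0.25, 0.48 ± 0.28, −0.06 ± 0.27 and 0.32 ± 0.31). JEN1, the lactate permease, passed (0.86 ± 0.26, adjusted p = 0.0363), but had 0.253 without 120 min replicate 2 and was lost without any T0 or 10 min array. Of 39 beta-oxidation and peroxisome genes 6 rose, FAA1 the most, and 6 adjusted over the list alone (median 0.53, adjusted p = 0.000134). Of 23 trehalose and glycogen genes 7 rose and 10 adjusted over the list alone (median 0.65, adjusted p = 2.03e-05, and adjusted p = 0.112 with an estimated correlation). Among them were GDB1, the glycogen debranching enzyme (1.54 ± 0.22), PIG2, a regulatory subunit for glycogen synthase (1.54 ± 0.29), and TPS1 of trehalose synthesis, 2.30-fold higher (adjusted p = 0.0509 without T0 replicate 1).

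Stress and quiescence genes rose in part. Of 42 Msn2/Msn4 targets 15 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.47, adjusted p = 0.000987, and adjusted p = 0.117 with an estimated correlation). ALD3 was at 1.46 ± 0.27, the kinase gene YAK1 at 1.32 ± 0.24 and PDE2, a cAMP phosphodiesterase, at −1.34 ± 0.25. Of 30 heat shock and chaperone genes 5 rose and 7 adjusted over the list alone (median 0.36, adjusted p = 0.00116, and adjusted p = 0.0556 with an estimated correlation), with APJ1 at 1.98 ± 0.31 and FES1 at 1.25 ± 0.23. Of 25 stationary phase genes 8 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.66, adjusted p = 0.00117, and adjusted p = 0.0556 with an estimated correlation). SPG4 was at 1.99 ± 0.28, SPG1 at 1.84 ± 0.25 and SRO9, at the floor, was at least 3.75-fold lower. Several stress markers did not pass. HSP12 had a signal of 7186 at T0 and 6560 at 120 min (−0.13 ± 0.24), HSP26 of 3895 and 4452 (0.19 ± 0.23) and SSA3 of 1047 and 1497 (0.52 ± 0.32). The highest deposited value of an array was 11234.4 to 15006.1 (1.34-fold), where the medians of the arrays differed 2.11-fold. How well changes are read near that top, as for HSP12, TDH3, ADH1, MFA1 and MFA2, was not tested. HSP104 was at 0.89 ± 0.30 (adjusted p = 0.0550), the polyubiquitin gene UBI4 at −0.12 ± 0.26, CTT1 at 0.49 ± 0.29, SNZ1 at 0.66 ± 0.23, GPD1 at −0.62 ± 0.24 and TSL1 at 0.25 ± 0.25. The regulators MSN4, GIS1 and RIM15 were at −0.66 ± 0.29, 0.56 ± 0.30 and −0.42 ± 0.25, and did not pass either.

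Relative to all other genes, lists of recycling, respiration and signalling were higher at 120 min, with few of their genes past the test. Not taken relative to them, the medians of autophagy and kinase signalling were negative as deposited and with spike-in scaling. That of the respiratory chain was negative as deposited. Of 33 autophagy genes 5 rose and 4 adjusted over the list alone (median 0.39, adjusted p = 0.00139, and adjusted p = 0.0725 with an estimated correlation). The mitophagy receptor ATG32 was at 1.54 ± 0.27 and ATG3 at 1.27 ± 0.22, and ATG1 and ATG8 did not pass (0.72 ± 0.29 and 0.43 ± 0.35). Of 14 vacuolar hydrolases 3 rose and 5 adjusted over the list alone (median 0.43, adjusted p = 0.0145, and adjusted p = 0.120 with an estimated correlation). PRB1 rose (0.88 ± 0.26, with adjusted p = 0.168 without 120 min replicate 1, and lost without either T0 array or the other 120 min array), and PEP4 was at 0.14 ± 0.24. Of 39 respiratory chain genes 1 rose and 0 adjusted over the list alone (median 0.25, adjusted p = 0.0286, and adjusted p = 0.164 with an estimated correlation). Of 38 kinase A, Snf1 and TOR signalling genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (median 0.34, adjusted p = 0.0462, but 0.120 with an estimated correlation and 0.0771 to 0.0940 under the 4 other scalings). GPA2, a G protein of glucose sensing, was at 1.78 ± 0.25.

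Ribosomal RNA and part of the other untailed RNAs were higher at 120 min too. Ribosomal RNA over the median transcript went from 5.74 at T0 to 16.3 at 120 min, and the 135 untailed RNA probe sets had a median of 0.86, with 54 higher and 0 lower. The ratio of 3' to 5' signal of actin, a sign of RNA integrity, was above its T0 value on every starved array of the same culture. It went from 1.4 to between 1.44 and 2.29 in culture 1 and from 1.24 to between 1.28 and 1.93 in culture 2, while that of TBP was higher in culture 1 and lower in culture 2. Left out, single arrays ended the 120 min list calls of vacuolar hydrolases (adjusted p = 0.0616 without T0 replicate 2), the respiratory chain (0.123 without T0 replicate 2, lost without 120 min replicate 1, and 0.0543 with a minimum mean of 50) and purine and pyrimidine synthesis (0.182 and lost without the same arrays). Kinase signalling reached 0.104 without 120 min replicate 1 and was lost without T0 replicate 2 and any 30 or 60 min array.

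**Figure D3:**
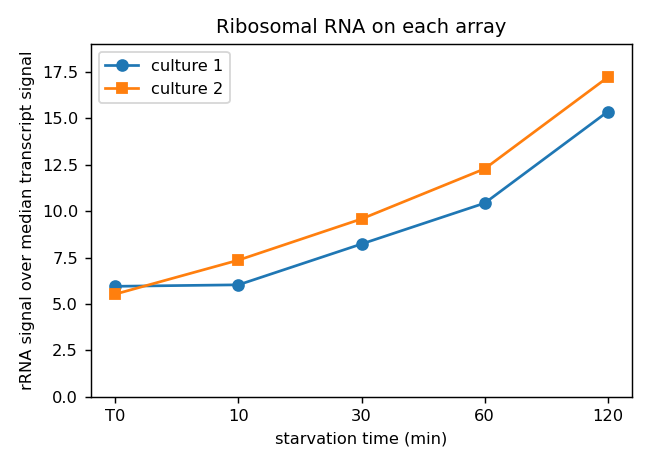
Geometric mean signal of the 10 probe sets of 18S and 25S ribosomal RNA divided by the median signal of the tested probe sets on each array (y axis, ratio of deposited intensities) against starvation time in min (x axis), with 1 line per culture. The ratio is 5.95 and 5.53 at T0 and 15.36 and 17.21 at 120 min.

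The counts at 120 min went to 301 higher and 456 lower without 120 min replicate 1 and 182 and 263 without 120 min replicate 2. They were 257 and 370 without T0 replicate 1, and 272 and 328 without T0 replicate 2. Of the 143 genes that the rule named and that passed at 120 min, 80 passed whichever array was left out, as did 36 of 96 at 60 min and 16 of 56 at 30 min. All 143, 96 and 56 had both starved arrays beyond both T0 arrays, which the rule demands of the largest rises and falls but not of list members and markers. The list medians of all lists that passed lay beyond T0 on both starved arrays too. With camera's estimated correlation 1, 4, 7 and 7 lists passed at 10, 30, 60 and 120 min, out of 6, 15, 23 and 20. These were ribosome biogenesis at each time, ribosomal proteins, polymerase subunits and Gcn4 targets from 30 min, and sulfur amino acids, gluconeogenesis and beta-oxidation from 60 min.

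**Figure D4:**
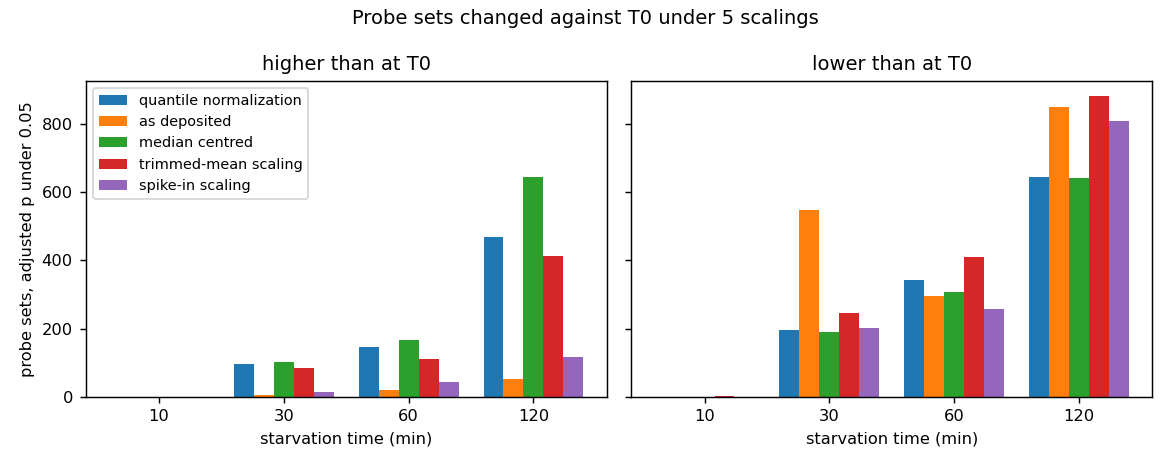
Probe sets with an adjusted p under 0.05 against T0 (y axis, left higher, right lower) at each starvation time in min (x axis), as bars for 5 scalings of the same arrays. At 120 min 470 probe sets are higher with quantile normalization, 52 as deposited, 645 median centred, 413 with trimmed-mean scaling and 116 with spike-in scaling.

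How many transcripts counted as higher depended on the scaling of the arrays. Quantile normalization sets equal distributions, so a rise here is one relative to the other transcripts of the array. With it 32.5%, 29.7% and 42.2% of the calls at 30, 60 and 120 min were rises. As deposited the shares were 0.7%, 6.6% and 5.8%, and with spike-in scaling 6.5%, 14.3% and 12.5%. Trimmed means gave 25.7%, 21.3% and 31.9%, and median centring 34.8%, 35.2% and 50.1%. The median of all probe sets moved as deposited by −0.175, −0.602, −0.313 and −0.468 at 10, 30, 60 and 120 min, and with spike-in scaling by −0.201, −0.108 and −0.312 at the last 3 times. Of the named genes that rose, 21 of 71 at 120 min, 11 of 39 at 60 min and 4 of 18 at 30 min passed under all 4 other scalings. Of those that fell, 70 of 72, 48 of 57 and 33 of 38 did. At 30 min those rises were SNR6, CIN5, NRS1 and YNCE0014W, and at 120 min they include FMP45, YNL194C, SNR6, NRS1, CIN5, BOP2, FAA1, ALD4, GDB1, APJ1, SPG4, SPG1 and GPA2. Of these, SNR6 and the tRNA YNCE0014W are RNAs without poly(A) tails, a class that was higher as a whole. Not taken relative to all genes, the medians of most rising lists turned negative as deposited, in 2 of 2 at 10 min, 7 of 7 at 30 min, 6 of 13 at 60 min and 4 of 10 at 120 min (19 of 32), and that of beta-oxidation at 60 min was −0.00. With spike-in scaling 2 did so, both at 120 min. They were autophagy and kinase signalling, the latter at −0.17 as deposited and −0.01 with spike-in scaling. Taken relative to all genes, the medians of the rising lists stayed positive under all 4 other scalings. Those 4 differ from each other only by a factor per array, which leaves such relative medians unchanged except through the floor. They are thus close to a repeat of the same check, and say nothing on whether the lists rose in absolute terms. Kinase signalling and purine and pyrimidine synthesis missed the threshold at 60 and 120 min under each of the 4 other scalings, and kinase signalling also with a floor of 50, a minimum mean of 50 or no filter (adjusted p from 0.0505 to 0.0800 over these). Sterol synthesis missed it at 30, 60 and 120 min under each of the 4, except with trimmed means at 120 min (adjusted p = 0.0395).

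The other 20 lists did not pass at 120 min. Glycolysis and fermentation had 1 of 23 genes higher and 2 lower (median −0.15, adjusted p = 0.583), also adjusted over the list alone, and the proteasome 1 of 36 lower and 0 adjusted over the list alone (median −0.01, adjusted p = 0.992). HXK2 was 3.81-fold lower (−1.93 ± 0.37), while HXK1 (−0.40 ± 0.23), ADH1 (−0.13 ± 0.23), PDC1 (−0.15 ± 0.25) and TDH3 (−0.25 ± 0.26, 11172 to 9418) did not pass. Hexose transporters had 3 of 12 higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.381). HXT1, HXT5 and HXT7 were at 0.91 ± 0.34, 0.12 ± 0.36 and −0.05 ± 0.22. Of the lists that passed at 60 min, mitochondrial ribosomal proteins had 1 higher and 0 adjusted over the list alone (median 0.17, adjusted p = 0.125) and the tricarboxylic acid cycle 1, also adjusted over the list alone (median 0.34, adjusted p = 0.124). The ubiquitin system had 4 higher and 3 lower, or 5 and 3 adjusted over the list alone (median 0.31, adjusted p = 0.212). Oxidative stress defence had 5 of 35 higher and 4 adjusted over the list alone (median 0.24, adjusted p = 0.140). Nitrogen catabolite repression (30 genes, median 0.27, adjusted p = 0.323) and phosphate starvation (16 genes, median 0.29, adjusted p = 0.178) each had 3 higher and 2 lower, also adjusted over the list alone. The iron regulon had 3 of 27 higher and 1 lower, also adjusted over the list alone (median 0.12, adjusted p = 0.417).

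Fatty acid and phospholipid synthesis had 8 of 30 higher and 2 lower, or 9 and 3 adjusted over the list alone (median 0.36, adjusted p = 0.106). The anaerobic cell wall and sterol uptake genes had 5 of 28 lower, also adjusted over the list alone (median −0.17, adjusted p = 0.208). DAN1, a cell wall mannoprotein of this list, was at −1.23 ± 0.24 and AAC3, at the floor on 1 of the 2 arrays, was at least 4.46-fold lower, while TIR1 was at −0.17 ± 0.22. Cell wall genes had 1 of 41 higher and 6 lower, or 1 and 4 adjusted over the list alone (median −0.00, mean −0.14, adjusted p = 0.544). Mitosis had 2 of 32 higher and 0 adjusted over the list alone (median −0.01, adjusted p = 0.945), and meiosis 3 of 29 and 2 (median 0.21, adjusted p = 0.307). RNA decay had 1 of 34 higher and 2 lower, or 0 and 2 adjusted over the list alone (median −0.15, adjusted p = 0.544). MATa-specific genes had 0 of 7 past the test, also adjusted over the list alone (median −0.42, adjusted p = 0.255). MATalpha-specific genes had 1 of 5 lower, or 1 higher and 2 lower adjusted over the list alone (median −0.08, adjusted p = 0.487). Haploid mating genes had 1 of 26 higher and 6 lower, or 1 and 7 adjusted over the list alone (median −0.12, adjusted p = 0.188). Of the 11 reference genes 1 fell, also adjusted over the list alone (median −0.02, adjusted p = 0.550), and ACT1 was at −0.02 ± 0.22.

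Between consecutive times few transcripts passed, and most of those did so between 10 and 30 min, where 1 rose and 6 fell by limma (381 and 525 unadjusted). ALT2, a homolog of alanine transaminase, rose 2.83-fold (1.50 ± 0.23, adjusted p = 0.0394). RPA12, at the floor on 1 of the 30 min arrays, fell at least 5.21-fold (adjusted p = 0.0105), NSR1 3.48-fold (−1.80 ± 0.29, adjusted p = 0.0407) and ILV1 of isoleucine synthesis 3.01-fold (−1.59 ± 0.24, adjusted p = 0.0394). The other 3 falls, named after their values were seen, were those of ARX1 (−1.92, adjusted p = 0.0105), FRS1 (−1.58, adjusted p = 0.0394) and ATX2 (−1.49, adjusted p = 0.0407). With the replicate block 7 rose and 50 fell, and as deposited 0 rose and 85 fell. Without any 10 or 30 min array 0 rose and 0 fell, without a T0 array 0 and 4, without a 60 min array 0 and 2, and without a 120 min array 1 and 12. The highest adjusted p was 0.122 for RPA12, without 30 min replicate 1, and 0.297 for ALT2, NSR1 and ILV1, without 10 min replicate 2.

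From 30 to 60 min 0 probe sets rose and 0 fell by limma (231 and 267 unadjusted, with a smallest adjusted p of 0.291). From 60 to 120 min 0 rose and 1 fell (158 and 172 unadjusted). The fall, named after its value was seen, was that of DCC1 of sister chromatid cohesion (adjusted p = 0.0135). It went from a signal of 42.7 at 60 min to the floor on both 120 min arrays, so that it fell by at least 1.83 in log2, and without any 60 or 120 min array 0 fell. Over all times together 665 probe sets changed by limma's F test (1575 unadjusted). That count was 421 and 398 without 10 min replicate 1 and 2, 402 without 120 min replicate 2, and 388 and 399 without T0 replicate 1 and 2. A return is a move by 10 min and back by 120 min. With quantile normalization and the floor of 12 it could not be called by limma, as 0 probe sets passed at 10 min. With a floor of 50, where 2 rose and 16 fell at 10 min, there were 3 returns. At unadjusted p and the floor of 12, 14 and 15 probe sets moved up and back or down and back, against a mean of 76 in simulations without any effect.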

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

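Probe sets outside the comparisons of the report were looked at because they carry signal on the same arrays. The test of array brightness for ribosomal RNA and the use of 3' to 5' ratios were chosen only after their values were seen, and the other tests in this part were chosen before. Ribosomal RNA control probe sets rose 2.83-fold over the median transcript from T0 to 120 min, as a geometric mean of 10. By limma over all probe sets 8 of the 10 were higher. An 18S probe set at 0.65 (adjusted p = 0.0797) and a 25S probe set at 0.20 (adjusted p = 0.689) did not pass. Of 1096 probe sets with no named gene, 76 passed at 120 min, 54 higher and 22 lower. Of 285 probe sets that name several genes, 45 passed at 120 min, 8 higher and 37 lower.

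The ratio of ribosomal RNA to the median transcript rose at every step in both cultures (means 5.74, 6.66, 8.88, 11.3 and 16.3). Array brightness is argued against, since the dim array of a time exceeded the bright one by 0.26 in log2, where 0.75 was needed. The amount of biomass was 100 mg at all starvation times, over which the ratio went on rising. A growing share of RNA without poly(A) tails in the labelled material may account for part of it. The 135 other untailed probe sets had a median change of 0.86, above the 95th percentile of 0.12 of matched random lists, in a test that could have failed. As deposited and relative to all probe sets their change was 0.80, where ribosomal RNA over the median transcript rose by 1.50 in log2. Many of the 84 tRNA probe sets are of a family type, which can read the same RNAs. The random lists treated probe sets as independent, so the bound of 0.12 may be too narrow. The 44 snoRNA probe sets alone had a median of 0.46, above 0.19 for their random lists. What stays open is why the share of untailed RNA would grow, by fewer tailed transcripts per cell, shorter tails or RNA handling. The 2 probe sets of mitochondrially encoded transcripts (median 1.03) are too few to decide, and starvation itself goes with the ratio. The ratio of 3' to 5' signal of actin, a sign of RNA integrity, does not close this: it was 1.4 and 1.24 at T0 and higher on each starved array of the same culture, but highest at 10 min in culture 1 (2.29) and at 60 min in culture 2 (1.93), while ribosomal RNA went on rising. That of TBP was higher than at T0 on all starved arrays of culture 1 and lower on all of culture 2.

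Ribosome biogenesis transcripts fell against all other genes by 120 min (median −0.88). Array brightness is argued against by a difference of −0.03 between the dim and bright arrays of a time, where −0.44 was needed. The signal level of these genes is argued against by 0 of 10000 random lists matched on signal that fell as far. One deviating T0 array is argued against by list medians of −0.83 and −0.89 against either of them (ratio 1.08). With these set aside, a response to starvation is a hypothesis, found and tested on the same arrays, and a link to the growing share of untailed RNA was not tested.

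Gene lists had moved by 10 min although no single transcript passed with quantile normalization and the floor of 12. With a floor of 50, 2 probe sets were higher and 16 lower, and with trimmed-mean scaling 0 and 1. Shared T0 arrays are argued against as the sole source, since changes at 10 and 120 min from different cultures, with no array in common, correlated across genes by 0.31 and 0.16, above the simulated 95th percentile of 0.02 (genes are not independent replicates). A change in 1 culture alone is argued against by ribosome biogenesis medians of −0.15 and −0.23 in the cultures (ratio 0.66). With the T0 arrays shared, the correlation was 0.58, where simulations without any effect gave a median of 0.50. Both T0 samples came from 50 mg of biomass and all starved samples from 100 mg. The 3' to 5' ratio of actin was also higher at 10 min (2.29 and 1.68) than at T0 (1.4 and 1.24), while that of TBP was so in culture 1 only. The simulated groups held no such shared difference. Neither test can tell an early response from the differences in biomass and in the actin ratio, which both cultures share. An early start of the later changes thus stays only a candidate explanation. The lists other than ribosome biogenesis stay uncertain, as their calls were lost without 1 array.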

How the results depend on the processing

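Trimmed-mean scaling, spike-in scaling and leaving out non-coding RNA were chosen after seeing the data, and the other alternatives before. Over all settings the named genes stayed on the same side of the threshold in 16642 cases, were weaker in 1139 and stronger in 222. For the lists these numbers were 3463, 148 and 65. None that passed in the main or the other setting reversed. Cases that passed in neither are counted among the 16642 and 3463, and their direction was not compared. For lists the direction is that relative to all other genes, which a factor per array could hardly reverse. Not taken relative to all genes, the medians of 19 of 32 rising lists were negative as deposited. Array number and signal over background set the limits here: 745 probe sets were too dim to test, and at 1.5-fold the simulated recovery was 1.8%. The cause was not tested for any change of a count below, except that a stricter threshold lowers the counts by construction. Counts are given as higher and lower where 2 are named, and compared with 95 and 197 at 30 min, 145 and 343 at 60 min, 470 and 644 at 120 min, 1 and 6 from 10 to 30 min, 0 and 1 from 60 to 120 min and 665 over all times. As deposited there were 4 and 547 at 30 min, 21 higher at 60 min, 52 higher at 120 min, 0 and 85 from 10 to 30 min, 1 higher from 30 to 60 min, 0 lower from 60 to 120 min and 2 lists lower at 10 min. Spike-in scaling gave 14 higher at 30 min, 43 at 60 min and 116 at 120 min, 0 and 72 from 10 to 30 min, 3 higher from 30 to 60 min, 0 lower from 60 to 120 min and 2 lists lower at 10 min. Trimmed-mean scaling gave 1 lower at 10 min, 20 lower from 10 to 30 min, 0 lower from 60 to 120 min and 1 list higher at 10 min. Median centring gave 2 higher from 10 to 30 min.

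A floor of 50 gave 2 and 16 at 10 min, 119 lower at 30 min, 92 and 226 at 60 min, 401 lower at 120 min, 7 and 20 from 10 to 30 min, 5 higher from 60 to 120 min, 329 over all times, 3 returns and 1 list higher at 10 min. Without a floor, log2 of value plus 1 gave 2 lower from 60 to 120 min, and plus 16 gave 15 and 61 from 10 to 30 min. No filter gave 110 lower at 30 min, 9 and 12 from 10 to 30 min and 394 over all times. A mean of at least 50 gave 7 and 48 from 10 to 30 min and 0 lower from 60 to 120 min. All probe sets gave 0 and 2 from 10 to 30 min. Trend and robust gave 14 and 59 from 10 to 30 min and 0 lower from 60 to 120 min. A fit of only the arrays compared, which gives no value for the F test and the return, gave 6 and 48 at 30 min, 77 and 228 at 60 min, 0 and 0 from 10 to 30 min and 0 lower from 60 to 120 min. An adjusted p under 0.01 gave 9 and 57 at 30 min, 40 and 131 at 60 min, 174 and 278 at 120 min, 0 and 0 from 10 to 30 min, 0 lower from 60 to 120 min and 203 over all times. With an estimated correlation 0 and 1 lists passed at 10 min, 0 and 4 at 30 min, and 2 and 5 at both 60 and 120 min. Fry, which tests a list without comparing it with other genes, gave 2 lists lower at 10 min and 11 higher at 30 min.

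Samples are paired by culture, and with the replicate block 7 rose and 50 fell from 10 to 30 min, and with a random replicate block 7 and 43. All other counts stayed within 1.5 times of the unblocked ones.

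With each array left out in turn, the lone array of a time was assumed to vary like the others. Counts ranged from 11 to 90 higher and 65 to 201 lower at 30 min, 36 to 157 and 127 to 359 at 60 min, and 182 to 486 and 263 to 670 at 120 min. They were 0 to 1 higher and 0 to 12 lower from 10 to 30 min, 0 to 1 lower from 60 to 120 min, 388 to 666 over all times, and 0 throughout at 10 min, from 30 to 60 min and for the return. Lists passing ranged from 0 to 2 higher and 1 to 5 lower at 10 min, 4 to 9 and 7 to 9 at 30 min, 8 to 13 and 8 to 10 at 60 min, and 7 to 12 and 9 to 10 at 120 min.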

Other observations

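Spike-in scaling, and the naming of the histones and of the classes of untailed RNA, were chosen only after values were seen. Single genes moved at 120 min within lists that did not pass. ISU1, a scaffold for iron-sulfur clusters, rose 4.64-fold from 567.3 to 2632 (2.21 ± 0.23, adjusted p = 0.000344, limma). GIT1, a glycerophosphoinositol permease, rose 3.63-fold (1.86 ± 0.24) and the phosphate transporter PHO89 3.03-fold (1.60 ± 0.22). Of the glucose sensors, SNF3, the high-affinity one, rose 2.21-fold (1.14 ± 0.24) and RGT2, the low-affinity one, fell 2.39-fold (−1.25 ± 0.26). PUT1 of proline use rose 2.96-fold (1.57 ± 0.27), TSA2, a peroxiredoxin, 2.38-fold (1.25 ± 0.24) and CIT3, a mitochondrial citrate synthase next to the floor on 1 T0 array, at least 3.79-fold. In lipid synthesis PAH1, the phosphatidate phosphatase, rose 3.91-fold (1.97 ± 0.31), while ELO3, a fatty acid elongase, fell 3.67-fold (−1.88 ± 0.30) and EPT1 2.73-fold (−1.45 ± 0.27). These calls held whichever array was left out. As deposited, PHO89, SNF3, PUT1 and TSA2 missed the threshold, and SNF3 and TSA2 did so with spike-in scaling as well.

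Of 26 haploid mating genes 6 fell and 1 rose at 120 min in these cells, which are MATa per the labels, and the list did not pass (adjusted p = 0.188). FAR1, which arrests the cell cycle in response to pheromone, fell 4.50-fold (−2.17 ± 0.32, adjusted p = 0.00143), the agglutinin subunit AGA1 3.05-fold (−1.61 ± 0.25) and PRM6 2.98-fold (−1.57 ± 0.25). The a-factor genes MFA1 and MFA2 were at 0.10 ± 0.24 and −0.05 ± 0.22 with T0 signals of 6763 and 6766, and did not pass. The alpha-factor gene MF(ALPHA)1 had a signal of 1121 at T0 and fell 3.19-fold to 351 (−1.68 ± 0.23). The MATalpha-specific genes were listed beforehand as ones that a MATa culture should lack, so what this probe set reads is uncertain. EXG1, a cell wall glucanase, fell 3.00-fold (−1.59 ± 0.22). Of the 4 measured genes of the histone list, HTB2 was at −2.03 ± 0.35 (adjusted p = 0.00292, 901.2 to 219.9) and HTB1, HHO1 and HTZ1 did not pass (−0.32 ± 0.25, 0.22 ± 0.30 and 0.19 ± 0.30).

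Among RNAs without poly(A) tails, 38 of 84 tRNA probe sets were higher at 120 min (median 0.97), 11 of 44 snoRNA probe sets (median 0.46) and all 4 snRNA probe sets (median 1.45), and 0 of each were lower. Many of the tRNA probe sets are of a family type and can read the same RNAs, so they are not 84 separate results. The snoRNA median was −0.14 as deposited and 0.01 with spike-in scaling, but 0.33 and 0.32 relative to all probe sets. Over the spike-ins, ribosomal RNA changed by 1.11 in log2 from T0 to 120 min (SD of the arrays 0.27 and 0.29) and the median transcript by −0.39 (SD 0.19 and 0.41). As these are hybridization spike-ins, the values do not give amounts of RNA per cell. Of 59 probe sets shared by ribosomal protein paralogs 30 were lower at 120 min and 0 higher (median −0.84).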
